A study of Homo sapiens with 2 samples.

How the data were processed

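Single-cell RNA was measured in 2 libraries, 1 WT and 1 KO for KIAA0319, each from 5 pooled organoids at day 43. Per the labels' protocols, organoids were dissociated with papain and libraries were made with the 10x Genomics 3' kit, which counts the 3' ends of transcripts. The submitters' processing notes name Cell Ranger 6.1.2, Seurat 4.3.0 and the build hg38, without their roles. The deposited values are raw counts of UMIs per gene and barcode for 36601 genes, as whole numbers in the files show. What was done before deposit beyond this is not given in the sources used here. Gene coordinates come from a GENCODE annotation of GRCh38, in which 34616 of the gene identifiers were found.

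Cells were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial counts, which left 3635 WT and 3875 KO cells. Scrublet called 2 WT and 3 KO doublets (0.051% and 0.0722% of barcodes), whose removal left 3633 and 3872 cells. So few calls mean that it did not work on these data, and doublets remain in the cells used. Counts were scaled per cell and log transformed, and 2000 variable genes were chosen without KIAA0319, mitochondrial, ribosomal protein, XIST and Y-linked genes. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 gave 27 clusters, with no batch correction (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1).

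Marker lists for 17 cell types, 39 gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. Several choices were made afterwards. A first clustering, with its cells per library, gene ratios and list medians, had been looked at before the naming rule was set. That rule needs 5 markers of a type, each at least 2-fold above the other cells (5 CPM added to both) with a UMI in at least 10% of a cluster's cells, and no other type with more markers among the 10 leading genes. A minimum of 3 had been considered first, and it is given as an alternative. Clusters in which over 25% of barcodes occur in both libraries were set apart as shared-source cells. Alternative clusterings were named afresh by the same rule. Because class sizes then varied widely, a further alternative kept the original names by majority of cells. This and the other added alternatives were chosen after seeing the data, as were the interval of a list's median and the bounds on free RNA from single genes such as MBP and EMX1. Classes and numbered clusters were compared with at least 50 cells in each library.

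UMIs were summed per library and class and given as CPM of that class. Intervals are exact Poisson for levels, exact binomial for shares, Newcombe for differences of shares and exact conditional for ratios, at 95%. A count of 0 was set to 3 in a ratio, which is then a bound, and was kept as 0 in the interval. A list's median used members with at least 20 UMIs, with its percentile among 10000 random lists of the same size in 20 bins of expression and an interval from 1000 Poisson redraws of the counts. Named genes are, in excitatory neuron-like cells and in progenitors, the 10 higher and 10 lower by the interval bound nearest to no difference, among genes with at least 100 UMIs, and in choroid plexus-like cells the first 5 each way. Up to 4 members per list with at least 50 UMIs could be named. Not every gene that the rule takes is given in the text. TMM factors came from edgeR 4.0.16 in R 4.3.3 and served as a scaling alternative, with no test. For cycling shares each cell was thinned to 3000 UMIs.

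The calculations were tested on simulated counts of a class in which 200 genes had known differences. The true log2 ratio was inside the 95% interval for 95.6% of 11395 genes, and 20 of the 20 genes ranked first were truly different. These counts were drawn from Poisson distributions, without variation between cells or cultures. The simulation therefore checks the calculations and does not show how reliable the ranking is in the real libraries. Alternatives covered the cell filter, doublets, clustering, scaling, list minimum and thinning.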

Results

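The data were single-cell RNA sequencing counts from brain organoids grown from WA09 (H9), an established human embryonic stem cell line, and labelled as cortex. There was 1 library from unedited (WT) organoids and 1 from organoids whose KIAA0319 gene had been knocked out (KO). Each library pooled 5 organoids at day 43, all from 1 batch. KIAA0319 encodes a membrane protein and lies in a region of chromosome 6 linked to dyslexia, and the series title asks about neuronal maturation, synapses and a network of dyslexia genes. The WT file held 3921 barcodes and 40881845 UMIs (unique molecular identifiers, 1 per captured RNA molecule), with a median of 9444 UMIs per barcode. The KO file held 4153 barcodes and 32669165 UMIs, with a median of 7070. After filtering, 3633 WT and 3872 KO cells were kept, with median mitochondrial shares of 1.46% and 1.81%. With 1 library per group, no difference below has a replicate check, no test was made, and every interval is a 95% interval that covers counting error only.

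KIAA0319 UMIs were present in the KO library in every class of cells examined. The gene (ENSG00000137261, chromosome 6, 24544104 to 24646155 on GRCh38, minus strand) had 933 UMIs in the kept WT cells, or 23.1 CPM (the standard scaling of UMIs by the total of the class; 21.7 to 24.7), and 626 in the KO cells, or 19.6 CPM (18.1 to 21.2). The log2 ratio of KO over WT was -0.24 (-0.39 to -0.09). These totals include 897 cells, 551 WT and 346 KO, in clusters whose barcodes recur in both libraries and which are called shared-source cells here. KIAA0319 stood at 164 CPM from 470 UMIs in the WT and 185 CPM from 278 UMIs in the KO shared-source cells. The ratio over all cells therefore also depends on how many shared-source cells each library held. In all other cells it stood at 12.4 CPM (11.3 to 13.5) in WT and 11.4 CPM (10.3 to 12.7) in KO, a log2 ratio of -0.11 (-0.32 to 0.09), which is within counting error. In excitatory neuron-like cells it was 26.8 CPM in WT from 139 UMIs and 20.4 CPM in KO from 69 UMIs, with a log2 ratio of -0.39 (-0.83 to 0.04). In the progenitor class the values were 7.70 and 8.61 CPM and the log2 ratio 0.16 (-0.35 to 0.67). Among the clusters compared by number, only cluster 12 had an interval that excluded 0. KIAA0319 was higher in KO there, with a log2 ratio of 1.09 (0.03 to 2.17) from 15 WT and 19 KO UMIs. Counts here come from the 3' end of transcripts and the edited part of the gene is not given in the sources used here, so these levels do not check the genotype labels.

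**Figure D1:**
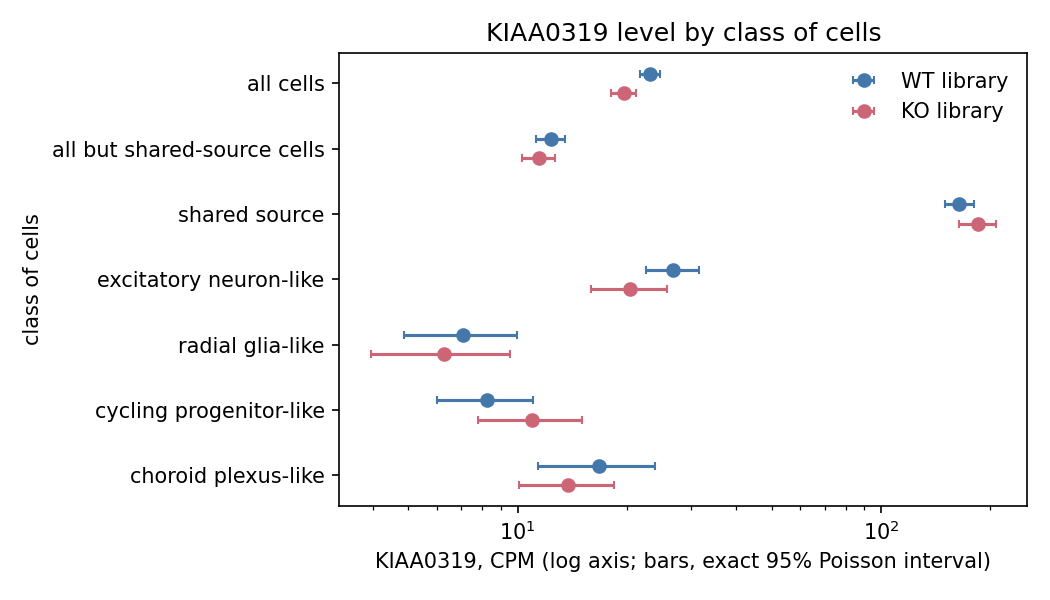
KIAA0319 level in CPM on a log axis, by class of cells, with WT in blue and KO in red, points for UMIs summed over a class and bars for exact 95% Poisson intervals. The intervals of the 2 libraries overlap in the classes drawn, while those of all cells together, 21.7 to 24.7 in WT and 18.1 to 21.2 in KO, do not. All cells include the shared-source cells, which held 470 of the 933 WT and 278 of the 626 KO UMIs. They were 15.2% of WT and 8.94% of KO cells. Without them the intervals overlap, at 11.3 to 13.5 in WT and 10.3 to 12.7 in KO.

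Among the genes near KIAA0319, DCDC2, another gene linked to dyslexia, was higher in the KO library over all organoid cells. Outside the shared-source clusters it had 709 UMIs in WT and 1105 in KO, a log2 ratio of 0.94 (0.80 to 1.08). In choroid plexus-like cells, where its level was 113 CPM in WT and 176 in KO, the log2 ratio was 0.65 (0.42 to 0.88), while it was 0.17 (-0.33 to 0.67) in progenitors and 0.23 (-0.93 to 1.36) in excitatory neuron-like cells, so the larger share of choroid plexus-like cells in KO could set part of the pooled ratio. GMNN, which encodes the replication inhibitor geminin, had a log2 ratio of -0.20 (-0.32 to -0.08), and ACOT13 one of 0.08 (-0.02 to 0.18). These neighbours were chosen by position after the data were examined.

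Cells of both libraries fell into the same kinds of clusters, of which 27 were found. Excitatory neuron-like cells made up 11.0% (9.98 to 12.05) of WT and 10.5% (9.59 to 11.5) of KO cells. Radial glia-like cells, named after the neural stem cells of the developing brain, made up 10.6% (9.59 to 11.6) and 11.9% (10.9 to 13.0). Cycling progenitor-like cells made up 7.65% (6.81 to 8.56) and 6.71% (5.95 to 7.55). The interval of the difference in share of all kept cells included 0 for each of these 3 classes. With the shared-source cells left out of the total, cycling cells made up 9.02% of WT and 7.37% of KO cells, a difference of -1.65 percentage points (-2.99 to -0.32). Over the alternatives the difference in their share, mostly of all kept cells, was between -3.49 and 0.941 points and left its interval in 8 of 22, so its direction depends on the processing. Among the classes named by markers, choroid plexus-like cells had the largest difference in share, at 2.45% (1.97 to 3.01) in WT and 5.58% (4.88 to 6.35) in KO, a difference of 3.13 percentage points (2.25 to 4.02). The class leaves out cluster 6, which had 7 choroid plexus markers and held 5.26% of WT and 5.50% of KO cells. With a stricter cell filter and clusters named afresh, the class held 205 WT and 309 KO cells, against 89 and 216 here. With 5 organoids pooled per library, a difference in makeup between single organoids cannot be separated from genotype. Clusters that the naming rule left unnamed held 53.2% of WT and 56.3% of KO cells. Several of them met the minimum of 5 markers but had more markers of another type among their leading genes. Clusters 5 and 12, with 7 and 8 excitatory neuron markers, were left out of the excitatory neuron-like class in this way. Of the unnamed clusters, cluster 9, with 12 radial glia markers and led by NALCN-AS1 and PRDM6, held 77 WT and 289 KO cells, or 2.12% and 7.46%. It is not counted in the radial glia-like class above, so that class does not hold all cells with radial glia genes. With WT clusters transferred to KO, the difference in share of radial glia-like cells was 6.79 points. The minimum of 5 markers, set after a first clustering had been seen, kept 3 clusters out of a class. They held 1.95% of WT and 1.94% of KO cells (most markers from the excitatory list), 2.67% and 1.16% (cortical hem list), and 1.24% and 1.14% (Cajal-Retzius list, though CA8 and CALB1 were among the leading genes).

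**Figure D2:**
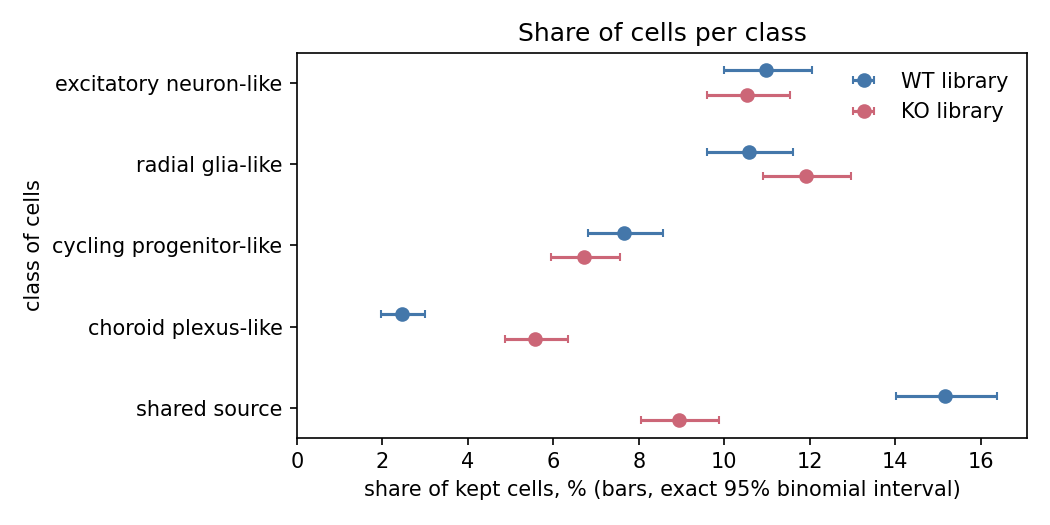
Share of kept cells in each class in percent, with WT in blue and KO in red and bars for exact 95% binomial intervals. Choroid plexus-like cells were at 2.45% in WT and 5.58% in KO, and shared-source cells at 15.2% and 8.94%.

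The organoid cells carried few transcripts of EMX1, a regulator of the dorsal forebrain, in either library. Outside the shared-source clusters EMX1 had 25 UMIs in WT and 2 in KO, while it stood at 6.65 and 8.63 CPM in the shared-source cells. Other members of the gene list of telencephalic identity were present there, with NR2F1 at 1154 and 887 CPM, LHX2 at 22.7 and 15.8 CPM and EMX2 with 151 and 171 UMIs. Genes of the hindbrain and dorsal neural tube were present too. PAX3 stood at 101 CPM in WT and 102 CPM in KO, HOXB2 at 34.6 and 54.9 CPM, HOXB3 at 19.9 and 30.1 CPM, and BARHL1 at 29.1 and 23.0 CPM. The class names used here say nothing of the brain region.

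In excitatory neuron-like cells, synaptic and dyslexia-associated genes were on balance slightly higher in the KO library, and their medians lay inside the range of random gene lists. Of 35 presynaptic genes 24 were higher and 11 lower in KO, with a median log2 ratio of 0.12 (0.08 to 0.21), at percentile 91.4 of 10000 matched random lists. SYN2 (0.59) and NRXN3 (0.51) were higher in KO and CPLX2 (-0.75) was lower. Of 35 postsynaptic genes 25 were higher, with a median of 0.13 (0.08 to 0.25) at percentile 94.9, including the glutamate receptor genes GRIN2A (0.68) and GRIA3 (0.48) and the scaffold gene DLG2 (0.59). Of 23 dyslexia-associated genes 15 were higher, with a median of 0.16 (-0.01 to 0.20) at percentile 95.6 that was as low as 0.051 over the alternatives. ROBO1, an axon guidance receptor, had 1060 CPM in WT and 1496 in KO, a log2 ratio of 0.50 (0.44 to 0.55), DOCK4 one of 0.49 (0.37 to 0.60) and FOXP2 one of -0.51 (-0.73 to -0.30). The median of all 9991 genes with enough UMIs in this class was 0.04.

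Genes of neuronal differentiation and the cytoskeleton were on balance lower in the KO library in the same cells. Of 23 genes 17 were lower, with a median of -0.12 (-0.16 to -0.07) at percentile 1.59. TUBB2A, a tubulin, was at 650 CPM in WT and 367 in KO, a log2 ratio of -0.83 (-0.92 to -0.73), NEFL, a neurofilament, had -0.42, while RBFOX1, a splicing factor, was higher with 0.49 (0.44 to 0.54). With a clustering at resolution 0.4 this median was -0.0038, or 0.032 with the original names kept.

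Nuclear genes of oxidative phosphorylation were lower in the KO library in excitatory neuron-like cells, progenitors and choroid plexus-like cells. In excitatory neuron-like cells 36 of 38 were lower in KO, with a median of -0.39 (-0.41 to -0.34) at percentile 0. The random lists were matched on size and expression only. A difference between the libraries tied to another gene property, such as gene length, was not tested for this or any other list. ATP5MF (-0.71), ATP5ME (-0.68) and ATP5F1E (-0.65), subunits of ATP synthase, were among them. In progenitors 35 of 38 were lower, with a median of -0.23 (-0.26 to -0.21), and in choroid plexus-like cells 37 of 38, with a median of -0.29 (-0.32 to -0.23). Mitochondrially encoded genes had a median of -0.18 (-0.25 to -0.14) in excitatory neuron-like cells, with 12 of 13 lower, and one of -0.0028 (-0.02 to 0.03) in progenitors. Glycolysis and hypoxia genes had a median of -0.19 (-0.29 to -0.11) in excitatory neuron-like cells, with GAPDH at -0.57 and MIF at -0.58, and one of 0.01 (-0.11 to 0.08) in progenitors. The former was 0.013 with the highest doublet scores removed and the clusters named afresh, which left 71 WT and 63 KO cells in the class, and -0.31 with the original names kept. The KO library had fewer UMIs per cell in this class, with a median of 7199.5 against 11750.

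**Figure D3:**
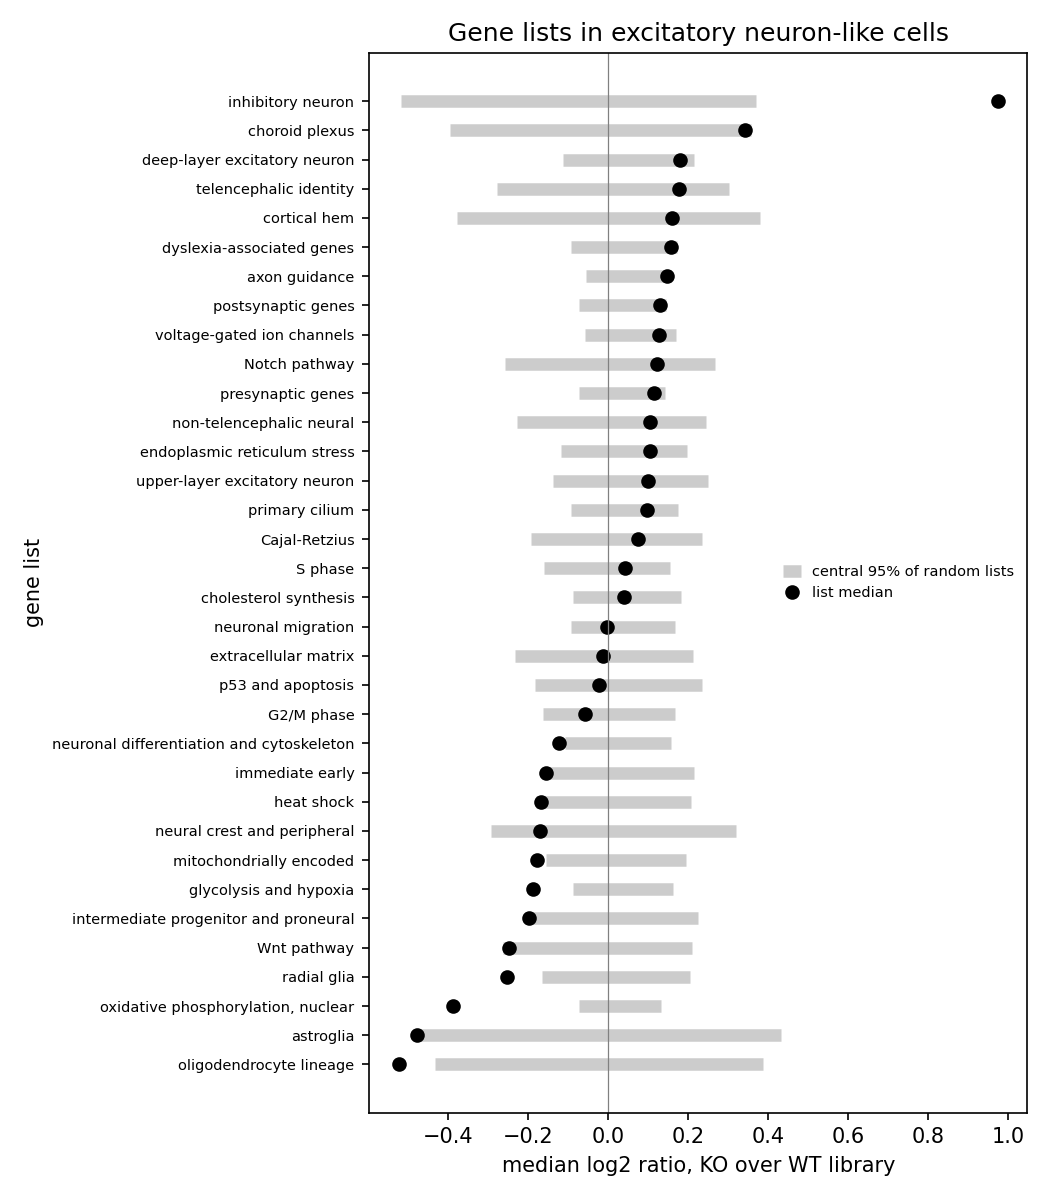
Median log2 ratio of KO over WT for each gene list in excitatory neuron-like cells, with dots for list medians and gray bars for the central 95% of 10000 random lists matched on size and expression. Oxidative phosphorylation lies at -0.39 against a random range of -0.07 to 0.13, while the synaptic lists lie inside their ranges.

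Single genes with the largest differences in excitatory neuron-like cells included noncoding RNAs that were higher in KO, and ARMCX1 and CFLAR, which were nearly missing in KO. LINC02511 (ENSG00000248869, chromosome 4) had 0 UMIs in WT and 135 in KO, which is at least 55.5-fold higher by the lower bound of the exact interval. Over the alternatives its log2 ratio was as low as 3.88, in those 71 and 63 cells, and 5.72 with the same scores removed and the original names kept. AC021504.1 had a log2 ratio of 2.17 (1.84 to 2.52) and LINC02315 one of 2.02 (1.78 to 2.26). LBX1, a regulator of hindbrain and spinal interneurons, had 2.17 (1.54 to 2.84), and SORCS1, a sorting receptor, 1.55 (1.30 to 1.81). AC079052.1, AC009315.1, PCAT7, FSIP2 and LINC01876 followed, with log2 ratios between 1.34 and 1.92. With the highest doublet scores removed FSIP2 had 0.061 and LINC01876 0.53 with clusters named afresh, and 1.30 and 1.34 with the original names kept, and over the alternatives SORCS1 was as low as 0.99. ARMCX1 (ENSG00000126947, chromosome X, 101550531 to 101554700) had 385 UMIs in WT and 2 in KO, a log2 ratio of -6.97 (-10.02 to -5.11). CFLAR, an inhibitor of caspase 8, had 116 and 4 UMIs, and PKIB, an inhibitor of protein kinase A, 356 and 45. PRELID2, DLK1, PAX3, RERGL, IAH1 and LY6H were lower in KO with log2 ratios between -2.79 and -1.36. LY6H was at 195 CPM in WT and 75.7 in KO. When cells with the highest doublet scores were removed and the clusters named afresh, PRELID2 had a log2 ratio of 0.71 and PAX3 one of 3.03, against -1.05 and -1.46 with the original names kept, and RERGL, with UMIs in 6 WT and 4 KO cells, had -0.87 and 2.12. Markers of other cell types also differed in this class. Of 7 inhibitory neuron genes 4 were higher, with a median of 0.97 (0.03 to 1.49) at percentile 100 that was as low as 0.050 over the alternatives, and their summed level was 65.7 CPM in WT and 63.9 in KO, while the medians were -0.25 for radial glia genes, with 4 of 15 higher and percentile 0.39 (-0.43 to 0.35 over the alternatives), -0.48 for astroglia, with 1 of 4 higher, and -0.52 for the oligodendrocyte lineage, with 0 of 5 higher. A difference in the makeup of this class was not separated from the synaptic and oxidative phosphorylation medians above. GAD2, an enzyme of inhibitory neurons, had 21 UMIs in WT and 41 in KO, and TTR, the main secreted product of choroid plexus, stood at 27.9 and 53.8 CPM.

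In the progenitor class, made of radial glia-like and cycling cells, mesenchymal and matrix genes were on balance higher in the KO library and proneural genes lower. Of 12 mesenchymal genes 11 were higher, with a median of 0.83 (0.66 to 0.97) at percentile 100. This median left its interval in 9 of 28 alternatives and was 0.037 when all deposited barcodes were used. Of 21 matrix genes 18 were higher, with a median of 0.42 (0.34 to 0.58) that was as low as 0.23 and left its interval in 4 of 28 alternatives. They included COL3A1 with 5 UMIs in WT and 51 in KO, and CCN2 with a log2 ratio of 1.01 (0.88 to 1.14). Of 9 choroid plexus genes 7 were higher, with a median of 0.78 (0.62 to 0.96). It was as low as 0.22 over the alternatives and left its interval in 9 of 28. TTR was at 175 CPM in WT and 653 in KO. TTR in excitatory neuron-like cells and the share of choroid plexus-like cells were higher in the KO library too, and free RNA and doublets were not separated from these values. Neural crest and peripheral genes had a median of 1.35 (0.93 to 1.60), with 4 of 4 higher, and inhibitory neuron genes one of 1.30 (0.42 to 1.81), with 4 of 5 higher, both at percentile 100, and they were as low as -0.11 and -0.38 over the alternatives. The summed level of the inhibitory neuron genes was instead lower in KO, at 36.3 CPM in WT and 21.2 in KO. Of 16 genes of the p53 response and apoptosis 11 were higher, with a median of 0.35 (0.17 to 0.43) and FAS at 1.34 (0.94 to 1.75). Of 14 intermediate progenitor and proneural genes 11 were lower, with a median of -0.35 (-0.48 to -0.19), SSTR2 at -1.15 and HES6 at -0.65. Of 28 alternatives, this median left its interval in 5 and turned sign in 6. Neuronal differentiation genes had a median of -0.21 (-0.34 to -0.14), with STMN2 at -1.10, and presynaptic genes one of -0.12 (-0.20 to -0.02), with CPLX2 at -1.57. Among the cycling clusters, cluster 13, with INSM1 among its leading genes, held 147 WT and 86 KO cells. With the clusters of the class weighted alike in both libraries, the proneural median was 0.18, the neuronal differentiation median 0.070 and the presynaptic median 0.053.

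Of single genes in progenitors, MIR924HG had 1794 UMIs in WT and 6 in KO. ARMCX1 had 419 and 0, TYW3 171 and 0, and CRYZ 120 and 0. By the lower bound of the exact interval they were at least 77.8-fold, 31.5-fold and 22.0-fold lower. TYW3 and CRYZ are neighbours on chromosome 1. CFLAR had 302 and 4, ZNF354C 109 and 4, and NOTUM, a secreted inhibitor of Wnt signals, 180 and 11. NPY, CRYGD and CRYAB, a small heat shock protein, were lower with log2 ratios of -2.67, -2.89 and -1.90. Over the alternatives NPY came as near to 0 as -0.66 and CRYAB as -0.13, and CRYAB left its interval in 16 of 26. LINC02511 had 4 UMIs in WT and 668 in KO, a log2 ratio of 7.92 (6.56 to 9.80), and NEK11, a kinase of the DNA damage response, 64 and 411. FIBIN (2.23) and PCDHB5 (2.67) were higher, with UMIs in 278 and 68 KO cells. Other genes higher in KO rested on few cells or on the clustering. PMCH (6.52) had its 126 KO UMIs in 5 cells and CDC20B (4.93) its 168 in 9 cells, against UMIs in 8 WT cells, and CDC20B was lower in KO in cluster 6 (-3.42). Over the alternatives the ratio was as low as 2.06 for PMCH, 0.13 for CDC20B, 0.78 for MT1E (3.19), 0.98 for PRDM6 (2.81) and 0.90 for CXCL14 (2.68). NALCN-AS1 had a log2 ratio of 2.57 (2.14 to 3.02), and one of -0.88 when cell cycle genes were left out of the clustering. In choroid plexus-like cells NEK11 (4.78) and LINC01876 (2.51) were higher, with UMIs in 175 and 127 of 216 KO cells, as were CRABP1 (4.09), SNTG1 (3.65) and TUBB2B (3.31), with UMIs in 31, 35 and 34 KO cells, so that a few cells could set these 3, and ARMCX1 (-6.55), IAH1 (-1.99), LY6H (-1.49) and TMBIM4 (-1.18) were lower.

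Within the progenitor class, cells with transcripts of MKI67 or TOP2A, which mark dividing cells, did not differ in frequency between the libraries beyond counting error. The class leaves out cluster 9, which had 12 radial glia markers and held 77 WT and 289 KO cells. Both genes are also among the markers by which the cycling clusters were named. After each cell was thinned to 3000 UMIs, 176 of 647 WT cells (27.2%, 23.8 to 30.8) and 194 of 675 KO cells (28.7%, 25.4 to 32.3) had such a UMI. The difference was 1.54 percentage points (-3.30 to 6.36). Over the alternatives it lay between -3.52 and 3.17 points and left its interval in 1 of 24. Thinning left out 15 WT and 46 KO cells. Without thinning the shares were 35.8% and 33.7%. In excitatory neuron-like cells, which should lack both genes, 1 of 394 WT cells and 0 of 384 KO cells had one after thinning, and 6 of 399 and 4 of 408 without it. Median depth was 13620 and 8445 UMIs in progenitors.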

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

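All tests in this part were chosen after the results had been seen. In the 6 shared-source clusters, 343 barcodes occurred in both libraries, which is 99.1% of the KO cells there, while 2 did among all other kept cells. The clusters were picked for these repeats, so their share there is no test of chance. Of the WT cells with such a barcode, 92.7% had their highest profile correlation with the same barcode in KO, against 0.292% at random, which is consistent with molecules of 1 further library being present in both files, and among KO cells of their own cluster 92.96% did, against 1.76% at random, which argues against chance repeats. Per repeated barcode, KO held a median of 0.594 times the UMIs of WT (5th to 95th percentile 0.545 to 0.624), and MBP stood at 287 CPM in these cells. No biological explanation was tested, since the design gives none.

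A further pattern is a set of 290 genes that were at least 2-fold apart between the libraries in many clusters. ARMCX1 was among the first 5 lower genes in 7 of the 11 clusters compared by number. The limit was set on the ratio alone, without its interval, and the same direction in each cluster was not required. With cells pooled, 133 genes of the set were higher and 157 lower in KO. How many genes would pass by counting error was not estimated. Gain or loss of 1 chromosome is argued against as the whole cause of this set by its spread. The chromosome with most of its genes, chromosome 6, which carries KIAA0319, held 8.42%, against 5.14% of all tested genes. Genes that passed by counting error would be spread over chromosomes too. The 2-fold limit keeps out smaller shifts, so this list cannot show whether a chromosome was gained. Over genes with at least 100 UMIs in the organoid cells, median log2 ratios per chromosome lay between -0.12 (chromosome 19) and 0.06 (chromosome 4). Chromosome 6 had 0.01. Counting, alignment or sequencing differences are argued against as the whole cause by the cells with repeated barcodes. There 103 genes of the set had a median absolute log2 ratio of 0.284, against 0.158 for other genes there and 0.763 in the other cells. With those other cells pooled, 0.763 is itself below the 2-fold limit. The genes had been picked for being apart over all clusters, the shared-source ones included. Both of their values could be raised by that choice, so 0.284 against 0.158 is no independent comparison. A part from counting, alignment or sequencing differences stays open, as does library preparation, which the repeated barcodes do not cover. The knockout and other differences between the 2 cultures cannot be told apart with 1 library per group.

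Another pattern is the presence of KIAA0319 UMIs in KO organoid cells, for which free RNA from the shared-source cells is a candidate source. A first bound, from the oligodendrocyte marker list, decided nothing, because it allowed 349% of the lower bound of the KIAA0319 level and the list as a whole stood at 98.0 CPM in the KO organoid cells themselves. Bounds from single genes were then taken, of which MBP allowed at most 38.4% of it and EMX1, the loosest of those tried, 49.5%. This argues against free RNA as the whole source, though the EMX1 bound rests on 2 UMIs and lies near the limit of 50% set for it. A part from free RNA, and transcripts that keep their 3' end after the edit, stay open.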

How the results depend on the processing

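The alternatives with the highest doublet scores removed, a minimum of 3 markers, the original names kept, shared-source cells left out, variable genes without library-wide genes, and clusters weighted alike were chosen after seeing the data. No paired analysis was possible because there is 1 library per group and both carry replicate 1. Of the KIAA0319 values, 61 stayed within their counting interval and none left it. The choroid plexus-like difference stayed between 2.48 and 3.40 points in 22 alternatives, and the oxidative phosphorylation median between -0.43 and -0.20 in excitatory neuron-like cells and between -0.28 and -0.18 in progenitors. Of list medians, 1737 stayed within their interval, 231 left it and 42 turned sign. Of named genes, 903 stayed, 131 left and 5 turned. Clusters named afresh gave 134 to 1247 excitatory neuron-like cells, against 807. Depth limits genes with few UMIs, and the KO library is the shallower. The cause was not tested for any value below.

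The share of excitatory neuron-like cells, KO minus WT, was -4.13 at resolution 0.4 (-3.83 with original names). That of radial glia-like cells was 6.79 with WT clusters transferred to KO, with either naming. That of cycling progenitor-like cells was 0.941 with all deposited barcodes, 0.349 with doublets kept and 0.265 with genes centred within each library, with either naming, 0.402 with WT clusters transferred to KO, and -3.49 without cell cycle genes. The cycling share of progenitors was -3.52 with WT clusters transferred and original names.

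In excitatory neuron-like cells, TMM scaling gave a presynaptic median of 0.071 and a neuronal differentiation median of -0.17. With the highest doublet scores removed and clusters named afresh, which left 71 WT and 63 KO cells, medians were -0.048 for neuronal differentiation (-0.089 with original names), 0.35 for radial glia (-0.01), 0.035 for intermediate progenitor (0.085), 0.013 for glycolysis and hypoxia (-0.31) and 0.48 for immediate early genes (-0.16), against -0.12, -0.25, -0.20, -0.19 and -0.15 in the fit used. The neuronal differentiation median was -0.0038 at resolution 0.4 and 0.032 there with original names. The intermediate progenitor median was 0.12 at resolution 0.4 (0.032 with original names), 0.030 with WT clusters transferred and 0.065 without cell cycle genes, with either naming, and 0.036 as a mean over cells. The immediate early median was 0.037 at resolution 0.4 and 0.038 with 100 UMIs per member. PRELID2 was 0.71 (-1.05 with original names) and PAX3 3.03 (-1.46) with the highest doublet scores removed, and RERGL -0.87 there and 2.12 with original names.

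In progenitors, all deposited barcodes, with either naming, gave medians of 0.088 for presynaptic, 0.18 for neuronal differentiation, 0.12 for intermediate progenitor, -0.15 for inhibitory neuron, -0.11 for neural crest and 0.046 for S phase genes. Resolution 0.4, with either naming, gave 0.060 for presynaptic, 0.34 for intermediate progenitor and 0.0013 for S phase genes. WT clusters transferred to KO gave 0.033 for presynaptic, 0.33 for intermediate progenitor and -0.024 for neural crest genes. Clusters weighted alike gave 0.053 for presynaptic, 0.070 for neuronal differentiation, 0.18 for intermediate progenitor and 0.067 for S phase genes. The inhibitory neuron median was -0.38 with the highest doublet scores removed, with either naming. NALCN-AS1 was -0.88 without cell cycle genes (-0.70 with original names).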

Other observations

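Clusters 3 and 10, which the naming rule left unnamed, had genes of inhibitory neurons among their leading genes. Cluster 3, with GAD1, PAX2 and LHX1 among its leading genes, held 5.75% of WT and 5.94% of KO cells, and cluster 10, with GAD2 and PAX2, held 4.57% and 4.70%. Cluster 4 held 7.82% of WT and 3.67% of KO cells, a difference of -4.15 percentage points (-5.22 to -3.10), and its cells had a median of 4620.5 UMIs and a median mitochondrial share of 0.126%. In choroid plexus-like cells the mitochondrially encoded genes had a median log2 ratio of -0.25 (-0.28 to -0.23), with 11 of 13 lower in KO. In progenitors 16 of 17 immediate early genes were higher in KO, with a median of 0.22 (0.12 to 0.35) that was as low as 0.038 over the alternatives and left its interval in 7 of 28, and all 13 heat shock genes were lower, with a median of -0.13 (-0.19 to -0.07) that came as near to 0 as -0.057 and left its interval in 9 of 28.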
